A study of Mus musculus with 4 samples.

How the data were processed

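RNA-seq values were analysed for 4 libraries of cultured thioglycolate-elicited mouse peritoneal macrophages, 2 labelled ApoE-/-/Ch25h+/+ (Ch25h_WT) and 2 labelled ApoE-/-/Ch25h-/- (Ch25h_KO). Per the labels' protocols, total RNA was extracted with a mirVana kit and sequenced as standard Illumina libraries on a NextSeq instrument. The submitters' processing notes name bcl2fastq, TopHat2 2.0.14, Cufflinks 2.2.1 and the mouse build mm9, with no settings. The gene annotation, strandedness, filters and any scaling between libraries are not given in the sources used here. The authors deposited a table of values per locus and library that fits FPKM in its range and decimals, with locus identifiers of the Cufflinks kind; its header does not name the unit. Because FPKM are not counts, no count test was run. The design had named a separate test for each unit, and the one for FPKM applied.

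The table held 24192 lines, and lines of the same locus were joined into 23735 loci, of which 340 carried more than 1 symbol and 202 symbols stood on more than 1 locus. Overlapping genes and near-identical copies cannot be told apart in values per locus without strand. Symbols were matched to current names in the RefSeq gene table of GRCm38.p6, with 99.4% of loci matched. This table is of another build than mm9, so it served only for names and for which genes neighbour each other, and no coordinates are given. GC content and transcript length were taken from GENCODE vM21 transcripts. No per-sample column was left out (0 columns).

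Relative depth was recovered from low values. The most common ratio of each library to Ch25h_WT replicate 1, among values under 0.5 FPKM, gave the relative depths. These were 1, 0.800, 0.824 and 0.770 for Ch25h_WT replicates 1 and 2 and Ch25h_KO replicates 1 and 2. After scaling by them, 95.3% of 2274 loci with a mean under 0.2 FPKM held whole multiples of a common fragment value in the 4 libraries. The tolerance was 0.01 fragments (widened in proportion to larger counts). With transcript lengths, 747 loci gave a median implied depth of 9350000 to 12100000 fragments. Low-count loci differed between replicates by more than sampling noise (mean chi-square per locus 1.23 within Ch25h_WT and 1.19 within Ch25h_KO, against 1.41 to 1.49 between groups), so no pair was treated as a single library deposited again. Across genes within the tables, which are not independent replicates, the Pearson correlation of log2 values was 0.997 within Ch25h_WT and 0.996 within Ch25h_KO.

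Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) among 10074 loci with a mean of at least 1 FPKM over the 4 libraries, with genotype as the single term and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, and ratios of mean FPKM are named as folds. Whole gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 of 34 lists with at least 5 tested members. With an estimated correlation, which rests here on 2 residual degrees of freedom, the smallest unadjusted p of any list was 0.0430, so none passed after adjustment over 30 lists, and these adjusted p do not rank the lists. The estimate was above the preset for some called lists, such as 0.063 for M1 markers, 0.13 for immediate early genes and 0.35 for resident macrophages. It was below 0 for others, such as -0.029 for LXR targets. Where members vary together by more than 0.01, camera p at the preset correlation are too small. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The 34 lists cover pathways, signs of RNA handling, and markers of other cell types, and each is reported with its result. Genes next to Ch25h were compared with the rest by Fisher's exact test, two-sided. The planned window of 5 Mb needs mm9 coordinates, which were not used here, so the fallback of the design was used, the 30 genes on each side.

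The named genes are Ch25h and Apoe, genes fixed in advance (Abca1, Abcg1, Nr1h3, Nr1h2, Srebf1, Srebf2, Nos2, Il1b, Il6, Tnf, Arg1, Mrc1, Retnla, Klf4 and others not reported here), and the 12 genes with the largest rise and the 12 with the largest fall. The last needed a pass at the adjusted threshold, at least 5 FPKM in the higher group and no overlap between groups, with predicted genes and short RNAs left out. From each list the members with the smallest p were added, at most 2 higher and 2 lower. Other genes named were chosen after their values were seen, namely further list members, the short RNA loci, and the genes beside Ch25h and Apoe.

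The gene and list tests were checked on simulated data with the 10074 loci, means and spreads of this comparison, in 10 runs with 200 changed loci. They recovered 73.3% of changes of 1.5-fold, 95.5% of 2-fold and 99.9% of 4-fold, and 2.77% of calls were false. Lists of 25 genes shifted by 0.3 were called in 10 of 10 runs, and 1 of 200 unshifted lists was called. Loci were simulated independently of each other, so the runs do not check the list test where members vary together. The 200 planted changes outnumber the 44 loci called in the data, so recovery in the data may be lower. Alternatives were a replicate block, each library left out, quantile and upper quartile scaling, pseudocounts of 0.1 and 0.01, other filters, limma with trend and robust, other thresholds, and an estimated correlation and fry for lists. Those chosen after the data were seen were removal of a trend over GC content and length, leaving out the Apoe cluster, adding Apoe to the LXR list, leaving Ly6c2 out of the monocyte list, and other windows of genes around Ch25h and Apoe. Tables were prepared with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1, and figures with matplotlib 3.10.9.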

Results

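RNA was sequenced from mouse peritoneal macrophages of 2 genotypes, both labelled as lacking apolipoprotein E. Ch25h encodes cholesterol 25-hydroxylase, the enzyme that makes 25-hydroxycholesterol, an oxysterol ligand of the liver X receptors (LXR). The comparison asked which transcripts differ when Ch25h is deleted on that background. The Ch25h_WT group (Ch25h present) and the Ch25h_KO group (Ch25h deleted) held 2 libraries each. The macrophages had been drawn into the peritoneal cavity by thioglycolate, a sterile irritant given at 3% 3 days before collection to mice 6 weeks old, and were then cultured. The labels name 12 mice per group and biological duplicates, and do not say how mice were divided between the libraries. Here n = 2 libraries for each mean ± SD, and p-values measure only the spread between these libraries, part of which may be technical. Each library listed between 13813 and 13970 loci above 0 FPKM (fragments per kilobase of transcript, relative to the mapped fragments of the library). The median implied depth was 12100000 and 9710000 fragments in Ch25h_WT replicates 1 and 2, and 10000000 and 9350000 in Ch25h_KO replicates 1 and 2. Saa3, an acute phase protein made by activated macrophages, alone held 16.3% to 17.2% of the total FPKM of a library.

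Ch25h itself was 63.3 and 65.3 FPKM in the Ch25h_WT libraries, and 4.25 and 5.53 FPKM in the Ch25h_KO libraries. It fell by 3.48 on the log2(FPKM + 1) scale (SE 0.12, limma adjusted p = 0.0031), and the lower group was the one labelled as lacking it. The Ch25h_KO libraries kept 0.0761 of the Ch25h_WT level, and the source of this remaining signal was not tested. Apoe, which encodes the apolipoprotein that carries cholesterol out of macrophages, was 614 and 610 FPKM in the Ch25h_WT libraries, and 3683 and 3373 FPKM in the Ch25h_KO libraries, although all 4 libraries were labelled ApoE-/-. Apoe rose 5.76-fold, with a log2 change of 2.52 (SE 0.066, limma adjusted p = 0.0013). FPKM of a whole locus do not tell a transcript of a disrupted allele from a functional one, so these values do not check the Apoe label or show that no functional Ch25h transcript was left, and a second difference between the groups at Apoe is not excluded. The apolipoprotein genes beside Apoe moved apart. Apoc1 fell from 272 ± 18.9 to 123 ± 1.19 FPKM (SD, n = 2 libraries per group; limma adjusted p = 0.016). Apoc4 was 23.7 ± 3.54 against 9.98 ± 0.733 FPKM and Apoc2 was 51.7 ± 0.920 against 74.7 ± 1.16 FPKM, each with limma adjusted p = 0.052.

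**Figure D1:**
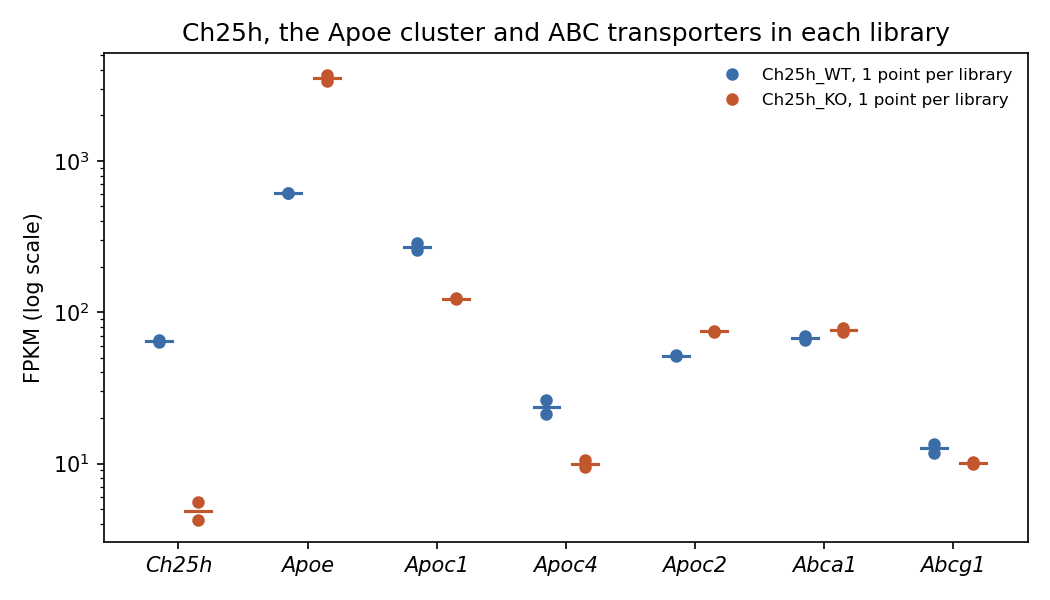
FPKM (log axis) of Ch25h, Apoe, Apoc1, Apoc4, Apoc2 and the cholesterol exporters Abca1 and Abcg1 in the 2 Ch25h_WT and the 2 Ch25h_KO libraries. Each point is a library and each bar a group mean; Ch25h is 63.3 and 65.3 FPKM against 4.25 and 5.53 FPKM, and Apoe is 614 and 610 FPKM against 3683 and 3373 FPKM.

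The genes that rose in the Ch25h_KO libraries included several of inflammatory macrophages. Nos2, the inducible nitric oxide synthase, rose from 36.4 ± 0.151 to 71.4 ± 0.832 FPKM. The T cell chemoattractant Ccl5 rose from 135 ± 10.7 to 326 ± 9.78 FPKM, and Csf3, the granulocyte growth factor G-CSF, from 98.0 ± 2.58 to 167 ± 2.70 FPKM (SD, n = 2 libraries per group). Ly6c2, a surface protein of inflammatory monocytes, rose from 2.91 ± 0.297 to 15.8 ± 2.14 FPKM, and it shares near-identical sequence with Ly6c1, so its level is uncertain. Tmem119 rose from 10.1 to 23.8 FPKM and AW112010 from 104 to 214 FPKM. Gja1 (connexin 43), Slamf1, Prok2, Fam26f and Rgs1 rose between 1.66-fold and 1.87-fold.

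The genes that fell included enzymes of glycolysis and markers of alternatively activated macrophages. Arg1, the arginase that competes with Nos2 for arginine, fell from 915 ± 7.43 to 584 ± 16.0 FPKM. Retnla, a secreted product of alternatively activated macrophages, fell from 905 ± 6.17 to 589 ± 0.441 FPKM. Egln3, an oxygen-sensing prolyl hydroxylase that is itself induced by hypoxia, fell from 22.9 ± 0.122 to 10.8 ± 0.183 FPKM. The glycolytic enzymes Tpi1 and Pfkl fell from 191 to 122 FPKM and from 86.1 to 55.8 FPKM, and the mitophagy receptor Bnip3 fell from 22.7 to 14.6 FPKM. Cav1 (caveolin 1), Wnt2, Arrb1 and Kcnn4 also fell, and were 1.52 to 1.97 times as high in Ch25h_WT.

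In all, 44 of 10074 tested loci passed (limma, Benjamini-Hochberg adjusted p under 0.05), of which 23 rose and 21 fell. At unadjusted p under 0.05 the count was 2107 loci, or 20.9% where 5% would pass with no change, with 945 higher and 1162 lower. The adjusted p of the genes named in the paragraphs on rises and falls lay between 0.0117 and 0.0434. Of the calls, 6 were loci of short RNAs, named here after their values were seen. Snora43 was listed at 0 in both Ch25h_WT libraries, and Snord15b, Snord35a, Snord89, Mir423 and Mir7-1 were listed at 0 in both Ch25h_KO libraries, so no fold is given. The count was 786 when the spread was modelled with limma's trend and robust options. Fewer than 44 passed with any library left out, where a group held a lone library. The loci that passed with a library left out also included many that were not among the 44. All 44 loci kept their direction in these settings, but they were picked from these same libraries, so a change of sign was unlikely. Most of the 44 did not pass without each library in turn, the exceptions being Ch25h, Apoe, Snora43, Snord35a and Mir423. The short RNA loci among these exceptions were listed at 0 in both libraries of a group, so they showed no spread there. Of 54 tested loci of short RNAs 6 were called, against 44 of all 10074 loci.

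Genes of cholesterol handling were compared next, because 25-hydroxycholesterol activates LXR and blocks the processing of SREBP2, which drives cholesterol synthesis. LXR targets other than Apoe, which the list as fixed does not hold, fell as a list (mean log2 change -0.20, camera adjusted p = 0.011), and adjusted p = 0.215 with an estimated correlation. With Apoe added, as chosen after the data were seen, the list did not pass (mean -0.070, SE over members 0.16, camera adjusted p = 0.090). Of 20 tested members, 1 passed over all genes (Apoc1, which fell), and 10 were lower and 1 higher when adjusted over the list alone. Nr1h3, which encodes LXR alpha, was 29.2 ± 2.17 against 20.4 ± 1.24 FPKM (limma adjusted p = 0.097). The cholesterol exporters did not pass, with Abca1 at 67.9 ± 3.10 against 76.5 ± 3.51 FPKM (limma adjusted p = 0.244) and Abcg1 at 12.6 ± 1.21 against 10.1 ± 0.153 FPKM (limma adjusted p = 0.160). Nr1h2, which encodes LXR beta, and Srebf1 did not pass either, at log2 changes of 0.061 and 0.032. Genes of lipid uptake and storage fell as a list (mean log2 change -0.11, camera adjusted p = 0.0082), and adjusted p = 0.215 with an estimated correlation. None of its 19 tested members passed over all genes with limma (8 had an unadjusted p under 0.05), and 6 were lower when adjusted over the list alone, namely the scavenger receptors Msr1, Olr1, Marco and Cd36, and the lipases Lipa and Lpl. Msr1 was 342 against 276 FPKM and Cd36 was 226 against 195 FPKM. Lists of resident large peritoneal macrophages, which shares Apoc1 with the LXR list, and of mast cells were also lower in these libraries (means -0.15 and -0.27, camera adjusted p = 0.010 and 0.0045, and adjusted p = 0.566 and 0.215 with an estimated correlation).

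Cholesterol synthesis and SREBP2 targets did not move as a list (camera adjusted p = 0.994, Up by the test, median log2 change 0.0035, mean -0.025). None of its 25 tested members passed with limma over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. Srebf2, which encodes SREBP2, had a log2 change of 0.061 and did not pass. None of the 11 tested genes of oxysterol metabolism and sensing passed, over all genes, adjusted over the list alone or at unadjusted p under 0.05 with limma (camera adjusted p = 0.901). Fatty acid synthesis did not pass as a list with camera (mean log2 change -0.10, camera adjusted p = 0.228) but passed with fry, which does not compare a list with other genes (Down, fry adjusted p = 0.0084), and 0 of its 12 tested members passed over all genes with limma (7 at unadjusted p under 0.05). Adjusted over the list alone, 5 of these members were lower (Scd2, Acaca, Fasn, Acly and Scd1) and Mlxipl was higher. The LXR call was lost without Ch25h_KO replicate 1 (camera adjusted p = 0.063). Without its members Apoc1, Apoc4 and Apoc2 the LXR list, then of 17 tested members, had a mean log2 change of -0.13 (camera adjusted p = 0.029).

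Of 26 tested M1 markers and inflammatory cytokines, 3 rose over all genes (Nos2, Ccl5 and Cxcl9, the last a chemokine induced by interferon gamma), and 14 were higher and 1 lower when adjusted over the list alone. Cxcl9 was low, at 0.330 ± 0.0518 against 1.84 ± 0.0540 FPKM, close to the filter of 1 FPKM. The list rose by a mean log2 change of 0.32 (camera adjusted p = 1.1e-09), and adjusted p = 0.215 with an estimated correlation. Il1b was 219 ± 11.7 against 310 ± 6.42 FPKM (limma adjusted p = 0.078), Il6 was 80.1 ± 3.96 against 102 ± 0.416 FPKM (limma adjusted p = 0.102), and Tnf, the member on the lower side, had a log2 change of -0.22 (limma adjusted p = 0.128). The feedback and signalling genes of NF-kB rose as a list by a smaller mean of 0.085 (camera adjusted p = 0.0045), and adjusted p = 0.215 with an estimated correlation. Of its 21 tested members 0 passed over all genes with limma (8 at unadjusted p under 0.05) and 1 was higher when adjusted over the list alone, the mRNA-degrading nuclease Zc3h12a at 57.1 against 73.7 FPKM. Neutrophil markers rose as a list in the same libraries (mean log2 change 0.25, camera adjusted p = 0.0033, and adjusted p = 0.215 with an estimated correlation). The call for monocyte markers rested on Ly6c2, and both calls were lost with no filter on low values (camera adjusted p = 0.106 and 0.183).

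M2 markers did not pass as a list with camera (camera adjusted p = 0.712) and passed with fry on the lower side (fry adjusted p = 0.042), and its median (-0.011) and mean (-0.0064) lay below 0 while the test's direction was Up. Arg1 and Retnla fell over all genes, and of 25 tested members 5 were higher and 4 lower when adjusted over the list alone. The lower ones also held Mgl2 and Clec7a, and the higher ones included Il10, the anti-inflammatory cytokine, at 37.1 against 53.3 FPKM. The mannose receptor gene Mrc1 was 5.94 ± 0.213 against 6.37 ± 0.167 FPKM and Klf4 was 4.81 ± 0.0407 against 4.47 ± 0.281 FPKM, and neither passed.

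Interferon-stimulated and antigen presentation genes were tested as 3 lists, each of which passed with camera on the higher side at the preset correlation and not with an estimated one. Of 50 tested interferon-stimulated genes, 1 rose over all genes (Zbp1, a sensor of Z-form nucleic acid, from 13.5 to 21.8 FPKM), and 9 were higher and 1 lower when adjusted over the list alone. Gbp2 was 51.1 against 85.8 FPKM and Isg15 was 46.3 against 66.7 FPKM. The list rose by a mean log2 change of 0.13 (camera adjusted p = 0.00013), and adjusted p = 0.215 with an estimated correlation. MHC class II presentation rose by a mean of 0.17 (camera adjusted p = 0.0065) and MHC class I presentation by a mean of 0.17 (camera adjusted p = 0.00013), and for each adjusted p = 0.215 with an estimated correlation. None of the 11 and 14 tested members passed over all genes with limma (6 in each at unadjusted p under 0.05), and 6 and 3 were higher when adjusted over the list alone. H2-Ab1 was 608 ± 13.6 against 794 ± 39.3 FPKM and the invariant chain gene Cd74 was 2696 against 3337 FPKM. Genes of the H2 family share similar sequence, which leaves their levels uncertain. The call for MHC class II was lost without Ch25h_KO replicate 2 (camera adjusted p = 0.073). The call for monocyte markers in the same libraries rested on Ly6c2.

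Of 24 tested genes of glycolysis and the response to hypoxia, 4 fell over all genes (Egln3, Tpi1, Pfkl and Bnip3), and 16 were lower and 2 higher when adjusted over the list alone. The lower ones included enzymes of several steps from glucose to lactate, with Pgam1 at 264 against 186 FPKM and Pgk1 at 307 against 240 FPKM. Also lower were Ldha at 1064 against 939 FPKM and the lactate exporter Slc16a3 at 87.6 against 62.1 FPKM. On the higher side were Vegfa, the angiogenic factor induced by hypoxia, at 27.1 against 34.2 FPKM, and Pfkfb3. The list fell with a mean log2 change of -0.29 (camera adjusted p = 3.6e-08), and adjusted p = 0.215 with an estimated correlation. Cell cycle genes fell as a list (mean -0.12, camera adjusted p = 0.0045) and so did heat shock genes (mean -0.13, camera adjusted p = 0.0065), and for each adjusted p = 0.215 with an estimated correlation. None of the 29 tested cell cycle genes passed with limma over all genes or adjusted over the list alone (27 were lower and 2 higher), and at unadjusted p under 0.05 the number was 5. Of 13 tested heat shock genes 0 passed over all genes with limma (5 at unadjusted p under 0.05), and Hsp90aa1 and Hsph1 were lower when adjusted over the list alone. Mast cell markers fell as a list in the same libraries (mean log2 change -0.27, camera adjusted p = 0.0045), and adjusted p = 0.215 with an estimated correlation. The cell cycle call was lost among loci with a mean of at least 5 FPKM (camera adjusted p = 0.065).

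**Figure D2:**
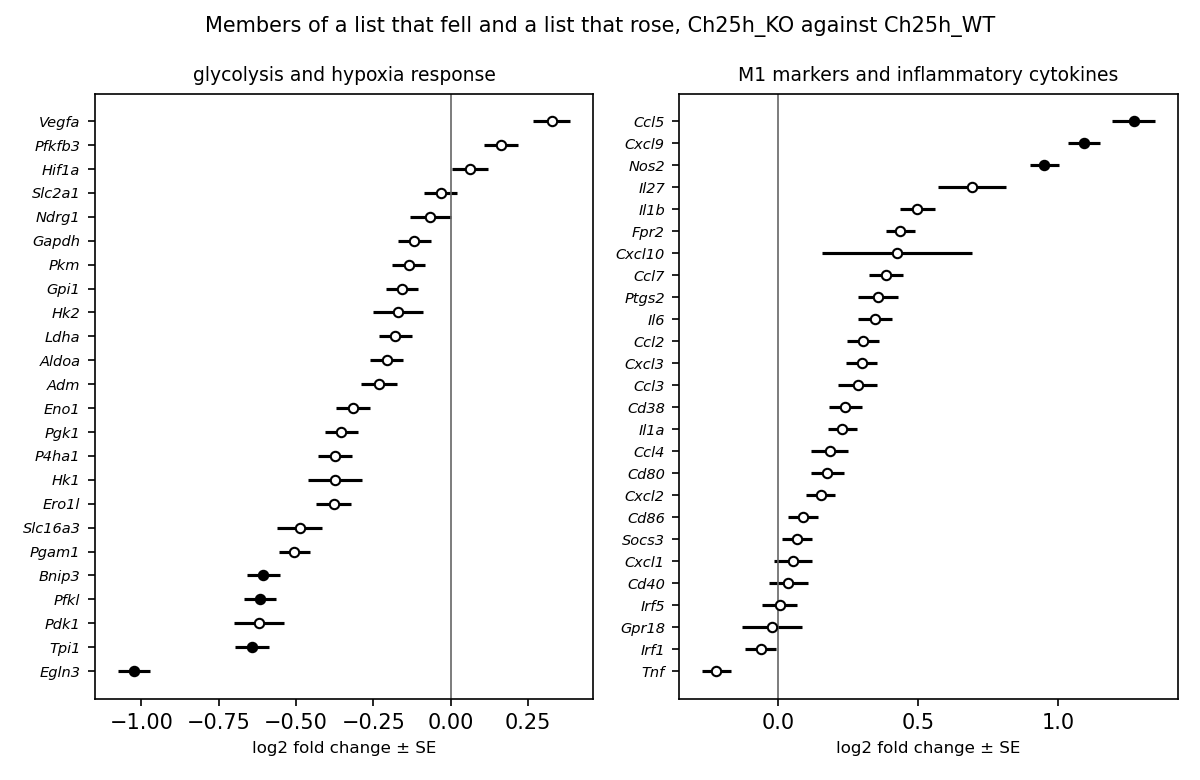
Log2 fold change of (FPKM + 1) in Ch25h_KO against Ch25h_WT for each tested member of the glycolysis and hypoxia list (left) and of the list of M1 markers and inflammatory cytokines (right), with bars of 1 SE from limma and filled points for members past the threshold over all genes. On the left 21 of 24 members lie below 0, with Egln3 at -1.02; on the right 23 of 26 lie above 0, with Ccl5 at 1.27.

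Markers of other cells differed between the groups. Of 10 tested mast cell and basophil genes, 0 passed over all genes with limma (8 at unadjusted p under 0.05), and 7 were lower and 1 higher when adjusted over the list alone. The mast cell proteases Cpa3, Tpsb2 and Cma1 were 31.3 against 19.1, 59.9 against 37.4 and 84.8 against 59.8 FPKM, while Hdc, which makes histamine and is also expressed by other myeloid cells, was 161 against 220 FPKM. The list fell (mean -0.27, camera adjusted p = 0.0045), and adjusted p = 0.215 with an estimated correlation. Markers of monocytes and recruited macrophages passed with camera (mean 0.26, SE over members 0.18, median 0.14, camera adjusted p = 0.010, and adjusted p = 0.215 with an estimated correlation), with 1 of 12 tested members past the threshold over all genes (Ly6c2), and 5 higher and 2 lower (Vcan among them) when adjusted over the list alone. Without Ly6c2, as chosen after the data were seen, the list did not pass (mean 0.088, SE 0.066, camera adjusted p = 0.071). Neutrophil markers rose as a list (mean 0.25, camera adjusted p = 0.0033, and adjusted p = 0.215 with an estimated correlation), with 0 of 11 over all genes (5 at unadjusted p under 0.05 with limma) and 3 higher when adjusted over the list alone, among them S100a8 at 61.4 ± 7.29 against 98.8 ± 0.274 FPKM and Lcn2 at 182 against 242 FPKM. Erythroid and platelet genes rose as a list (mean 0.43, camera adjusted p = 0.0082, and adjusted p = 0.215 with an estimated correlation). Of 6 tested members 0 passed over all genes with limma (3 at unadjusted p under 0.05). Adjusted over the list alone 2 were higher, Hbb-b1 at 22.9 against 29.1 FPKM and Pf4 at 1653 against 2092 FPKM. The 1 member on the lower side, the platelet gene Gp1bb, was 2.66 against 2.63 FPKM, so a rise of platelets is not shown. Genes of resident large peritoneal macrophages fell as a list (mean -0.15, camera adjusted p = 0.010), and adjusted p = 0.566 with an estimated correlation. Apoc1 was the 1 of 19 that passed over all genes, and 5 were lower and 2 higher (Icam2 and Timd4) when adjusted over the list alone. Without Apoc1 the list, then of 18 tested members, had a mean of -0.093 (camera adjusted p = 0.041). The erythroid call was lost without Ch25h_WT replicate 1 (camera adjusted p = 0.066) and the resident macrophage call without Ch25h_WT replicate 2 (camera adjusted p = 0.071). With no filter on low values the monocyte and neutrophil calls were lost (camera adjusted p = 0.183 and 0.106).

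Immediate early genes, which are induced within minutes of handling or stimulation, rose as a list (mean 0.18, camera adjusted p = 2.8e-06), and adjusted p = 0.215 with an estimated correlation. Of 23 tested members Egr1 rose over all genes, from 20.9 to 33.2 FPKM, and 9 were higher when adjusted over the list alone, among them Fos and the phosphatase gene Dusp1 at 242 against 344 FPKM. This call stood beside those of the inflammatory and glycolysis lists in the same libraries.

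**Figure D3:**
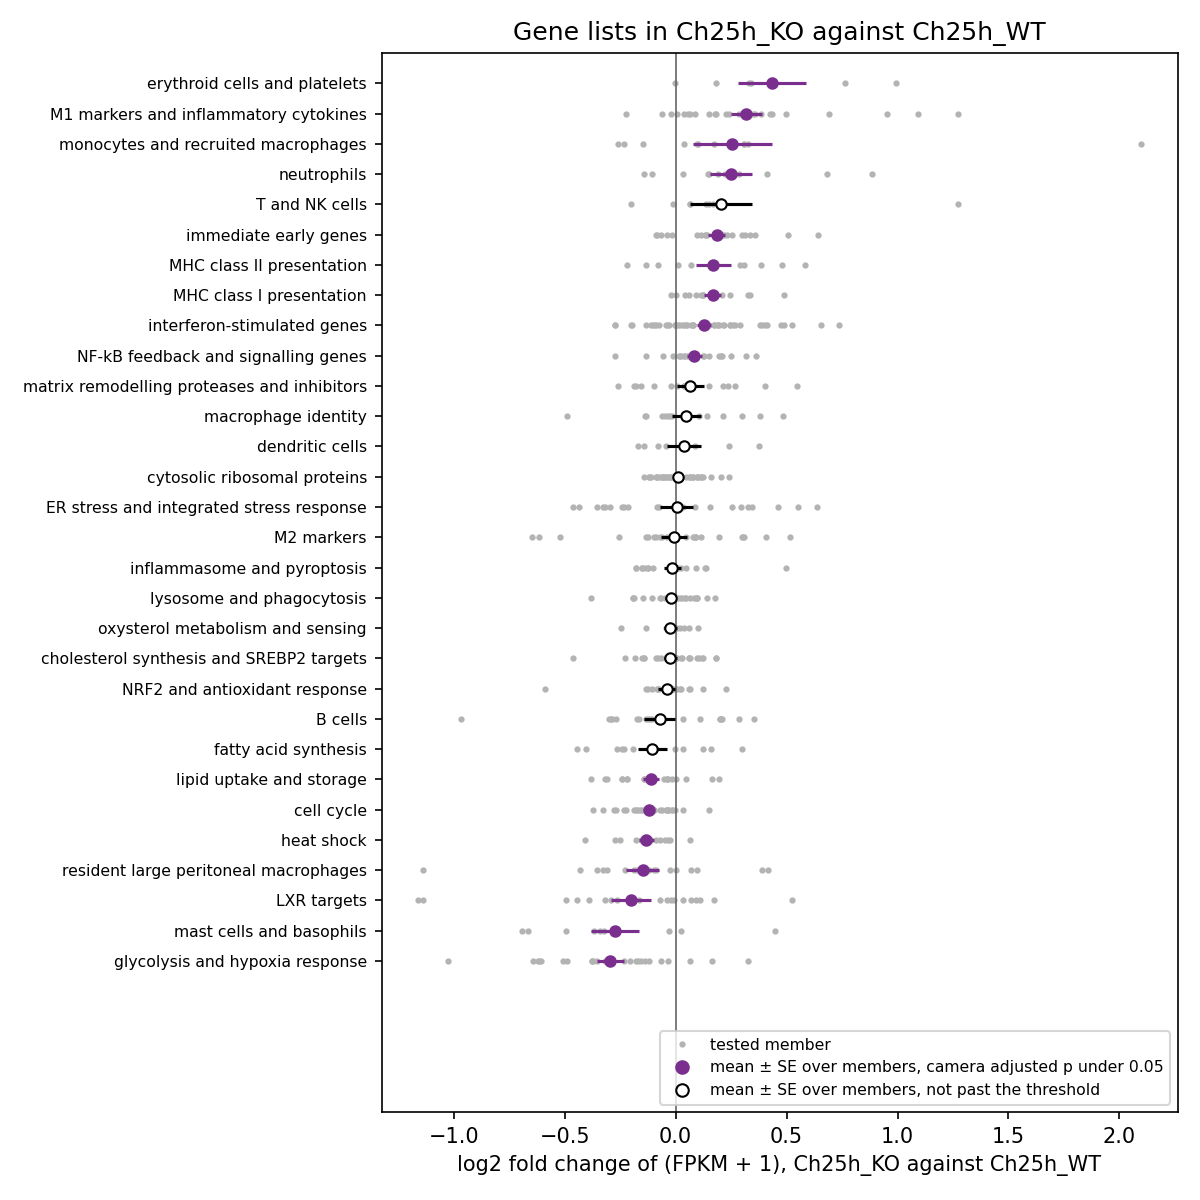
Log2 fold change of (FPKM + 1) in Ch25h_KO against Ch25h_WT for the 30 lists tested with camera, 1 line per list. Grey points are tested members, large points their mean with a bar of 1 SE over members, and filled ones lists past the threshold; the means run from -0.29 for glycolysis and hypoxia to 0.43 for erythroid cells and platelets.

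Genes next to Ch25h were compared apart, because a deletion made in cells of another strain can carry flanking DNA of that strain. Of the 6 tested genes among the 30 on each side of Ch25h in the gene order of GRCm38.p6, 0 passed with limma, against 41 of 10063 others (Fisher's exact test, two-sided, p = 1). The others left out Ch25h and the Apoe cluster. With 0.41% of them called, 6 genes are too few to show or exclude an excess (interval of the odds ratio 0 to 214). At unadjusted p under 0.05 the number was 2 of 6, Lipa and Fas. Lipa, the lysosomal acid lipase, was 149 ± 0.0205 against 114 ± 1.25 FPKM, and the death receptor gene Fas was 65.1 ± 2.48 against 50.2 ± 0.198 FPKM. Fas was named after its value was seen. Among 30 protein-coding genes on each side, a window also chosen after the data were seen, 0 of 25 tested genes passed, and 10 of 25 had an unadjusted p under 0.05, against 2092 of 10044 others (Fisher's exact test, two-sided, p = 0.026, odds ratio 2.53).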

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

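The settings without the Apoe cluster, without the GC and length trend, with Apoe added to the LXR list, without Ly6c2 in the monocyte list, and with 10 or 60 genes or 30 protein-coding genes on each side of Ch25h were chosen after the data were seen. Of 44 loci called, all 44 kept their direction in every setting that tested them. They were picked from these same libraries, so this is little evidence of stability. The count was 43 with quantile normalization, 46 with upper quartile scaling, 30 with a pseudocount of 0.1 and 42 without the Apoe cluster. It was 24 with a pseudocount of 0.01, 18 with no filter, 175 among loci with a mean of at least 5 FPKM, 786 with limma's trend and robust options (43 of the 44 shared), 256 at adjusted p under 0.1, 16 at a change of at least 2-fold and 75 without short and predicted genes. The cause of these moves was not tested. The count ranged from 13 to 21 with a library left out, where the lone library is assumed to vary like the other group: 15 and 21 without Ch25h_WT replicate 1 or 2, 13 and 14 without Ch25h_KO replicate 1 or 2. In each fit with a library left out, many of the loci called were not among the 44, so these calls are not a subset of the 44. Deviations of same-numbered libraries correlated at 0.012, so the replicate numbers were not taken as pairs, and the replicate block gave 6 loci. Ch25h and Apoe passed in each setting that tested them. Of 16 lists called, 0 passed with an estimated correlation, 11 passed with fry, which called 15 lists and tests whether genes of a list move one way, and 16 with quantile normalization. With fry the calls lost were interferon-stimulated genes, cell cycle, MHC class II presentation, resident macrophages, and erythroid cells and platelets (fry adjusted p = 0.056, 0.056, 0.061, 0.062 and 0.097). The calls gained were fatty acid synthesis (Down, 0.0084), M2 markers (Down, 0.042), macrophage identity (Up, 0.023) and matrix remodelling (Up, 0.049). The number of lists called was 15 with Apoe added to the LXR list and 15 without Ly6c2 in the monocyte list, each losing that list. For M2 markers camera gave Up at the same mean of -0.0064. It compares a list with the other genes, and the median log2 change of all loci was lower, at -0.014. Near Ch25h the count was 0, and at unadjusted p under 0.05 it was 2 of 6 with 30 genes on each side, 2 of 4 with 10, 7 of 20 with 60, and 10 of 25 with 30 protein-coding genes on each side (Fisher's exact p = 0.611, 0.194, 0.162 and 0.026). The planned windows of 1 and 10 Mb were not run, since mm9 coordinates were not used here. With 2 libraries per group of 9350000 to 12100000 fragments each, 73.3% of simulated changes of 1.5-fold were recovered among loci above about 5 FPKM. Smaller changes, changes of lower loci and loci that vary together were not simulated.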

Other observations

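In this part, the tests of Apoe and the choice to test 3 further gene sets were made only after the results were seen; the members of those sets were written down before their own values were looked at. Genes of the ER stress and integrated stress response list moved apart in the Ch25h_KO libraries. The list did not pass (camera adjusted p = 0.994, Down by the test, median log2 change -0.076, mean 0.0047). Of 21 tested members Chac1, which degrades glutathione, rose over all genes, and 8 were higher and 8 lower when adjusted over the list alone. The higher ones included the transcription factor Atf4 and its targets Trib3, Ddit3 and Asns, with Asns at 83.4 against 106 FPKM and Chac1 at 20.9 ± 1.03 against 33.0 ± 0.131 FPKM (SD, n = 2 libraries per group). The lower ones were chaperones and folding enzymes of the endoplasmic reticulum, with Hsp90b1 at 367 ± 0.722 against 265 ± 2.15 FPKM and Hspa5 at 895 against 713 FPKM. The hypothesis that the ATF4 arm was higher and the folding arm lower was then examined in genes outside the list. These genes belong to the same arms and were read in the same 4 libraries. A like direction was therefore probable and is not independent support. Of 22 tested ATF4 targets, 20 were higher (mean log2 change 0.20, camera adjusted p = 1.7e-09), among them Phgdh, Shmt2 and Mthfd2 of serine and folate metabolism. Of 18 tested folding genes, 16 were lower (mean -0.17, camera adjusted p = 1.5e-05), among them Hyou1 and Canx. With an estimated correlation the unadjusted p was 0.022 and 0.041, and adjusted p = 0.046 for both over only 3 sets, a smaller correction than the one over 30 lists. None of these genes passed over all genes with limma (at unadjusted p under 0.05, 16 ATF4 targets were higher and 1 lower, and 9 folding genes were lower). Adjusted over each set alone, 11 ATF4 targets were higher and 1 lower, and 9 folding genes were lower. The sets' means differed by 0.377, in the direction of the hypothesis. Whether protein folding or amino acid supply changed was not measured. In the same libraries immediate early genes rose and heat shock genes fell as lists (means 0.18 and -0.13). Mast cell markers fell and neutrophil markers rose (means -0.27 and 0.25). Effects of handling and of cell makeup on these sets were not tested and stay open.

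A further set was used to see whether the fall of glycolysis genes extended to other genes of the hypoxia response. It was read in the same libraries, so it is not independent support either. Of 21 tested genes, 17 were lower, with a mean log2 change of -0.207 (camera adjusted p = 4.1e-05), and adjusted p = 0.046 with an estimated correlation. That value was adjusted over 3 sets, and at unadjusted p it was no smaller (0.046) than the glycolysis and hypoxia list (0.043), which did not pass over 30 lists. Egln1, Gys1, Gbe1 and P4ha2 were among the lower ones, and Ddit4, which ATF4 also induces, was higher at a log2 change of 0.36. With limma 0 passed over all genes (10 lower and 1 higher at unadjusted p under 0.05), and 8 were lower and 1 higher when adjusted over the set alone. A lower activity of hypoxia-inducible factors would go with this value, but it is a hypothesis and was not measured. In the glycolysis and hypoxia list 21 of 24 tested members were lower, while Vegfa and Pfkfb3 were higher (log2 changes 0.33 and 0.16). Oxygen and cell density in the cultures are not given, so a culture effect stays open.

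Other lists did not pass with camera. Matrix remodelling genes had a camera adjusted p = 0.239 and passed with fry (Up, fry adjusted p = 0.049), with 0 of 15 tested over all genes (8 at unadjusted p under 0.05 with limma), and 5 higher and 2 lower when adjusted over the list alone; Timp1 was 84.2 against 123 FPKM. Macrophage identity genes had a camera adjusted p = 0.385 (median -0.021, mean 0.049, Up) and passed with fry (Up, fry adjusted p = 0.023), with 0 of 14 over all genes (6 at unadjusted p under 0.05), and 3 higher and 1 lower when adjusted over the list alone; Cd14 was 5233 against 6810 FPKM and Lgals3 was 277 against 197 FPKM. Inflammasome genes (0 of 18 over all genes, 2 at unadjusted p under 0.05, 1 higher adjusted over the list alone, Il1b) had a camera adjusted p = 0.847. NRF2 genes (0 of 19, 2 at unadjusted p under 0.05, 0 adjusted over the list alone) had 0.712, and lysosome and phagocytosis genes (0 of 26, 6 at unadjusted p under 0.05, 1 lower adjusted over the list alone, Lipa) had 0.994. Cytosolic ribosomal proteins (0 of 39, 2 at unadjusted p under 0.05, 0 adjusted over the list alone) had 0.492, with a median of -0.0051 and a mean of 0.012, Up. Among cell types, B cell genes (0 of 19, 9 at unadjusted p under 0.05, 1 higher and 2 lower adjusted over the list alone) had 0.640. T and NK cell genes (Ccl5 alone of 9 over all genes, adjusted over the list alone and at unadjusted p under 0.05) had 0.0973, and passed in 3 other settings, at 0.0362 with a replicate block, 0.0098 with no filter on low values (26 members tested) and 0.0452 without Ch25h_WT replicate 2. Dendritic cell genes (0 of 7, 4 at unadjusted p under 0.05, Cd209a higher adjusted over the list alone) had 0.822, with a median of -0.045 and a mean of 0.038, Up. Too few members were tested for camera in 4 lists, and with limma 0 passed over all genes in each. Adjusted over the list alone, 0 of 3 histone genes passed (1 at unadjusted p under 0.05) and 0 of 1 sex-linked gene (Xist, 0 at unadjusted p under 0.05). Of 4 eosinophil genes 2 were higher (2 at unadjusted p under 0.05), and of 3 mesothelial and fibroblast genes 2 were higher and 1 lower (3 at unadjusted p under 0.05).

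Apoe rose 5.76-fold in libraries whose labels call both groups ApoE-/-. Reads assigned to Apoe in place of its neighbours do not account for it, since Apoc1, Apoc4 and Apoc2 together lost 140 FPKM, 0.0479 of the 2916 FPKM that Apoe gained. Nor does a shared rise of the whole cluster through LXR, since 2 of the 3 Apoc genes (Apoc1 and Apoc4) were lower at unadjusted p under 0.05 with limma. That bound was written after these values were seen, and an effect of LXR on Apoe alone is not excluded. A different Apoe allele in the mice of the Ch25h_KO libraries stays open at the ratio of 5.764, because values by exon or allele were not used here, and with it how much of the other differences may follow Apoe rather than Ch25h. Of 20 tested genes among the 30 on each side of Apoe, the cluster left out, 0 passed with limma and 8 had an unadjusted p under 0.05 (Fisher's exact test against the rest, two-sided, p = 0.0497).

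The fall of the glycolysis and hypoxia list (mean -0.29) was set against technical explanations. Removing the trend of log2 changes over GC content and transcript length left 0.998 of the mean, with values for 100% of its tested members, although that trend was small (median size 0.033). Under quantile and upper quartile scaling the list kept at least 0.976 of its mean, so scaling around Saa3 does not account for the fall either. Effects of culture and of cell makeup were not tested for this list and stay open, and a biological difference between the genotypes is a hypothesis among them.

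Ly6c2 rose by 12.9 FPKM in the Ch25h_KO libraries. Reads moved to it from its paralogs do not account for the rise. Ly6c1 lost 0.231 FPKM, while Ly6a and Ly6i gained 17.5 and 1.78 FPKM (together a loss of -1.48 relative to the gain of Ly6c2). The test looked only for a loss, so reads shared with a paralog that rose, such as Ly6a, are not excluded. More inflammatory monocytes in the cultures could not be excluded. The 8 other monocyte markers under 50 FPKM had a median log2 change of 0.0976, below the bound of 1.05 set for them in advance, and Vcan was among the lower ones. That bound was set too high, as judged after the values were seen: the markers had a median of 13.3 FPKM in Ch25h_WT, against 2.91 for Ly6c2, and 1 of them lay as low, so a small share of added cells would be hidden.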
